A study of insect gut metagenome and Drosophila melanogaster with 110 samples.

How the data were processed

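The 30 RNA-seq libraries came from pools of 15 midguts at 13 days, and the 80 samples of 16S sequencing from pools of 5 midguts at 3, 6 and 10 days. The deposited RNA files hold raw read counts per gene, 1 file per library. They came from TruSeq stranded mRNA libraries, per the labels' protocols, and the tools named are cutadapt, TopHat2 2.1.0 and HTSeq 0.6.1p1 with the BDGP6 genome build, per the submitters' processing notes. The deposited 16S file holds raw read counts of 974 OTUs, groups of reads that stand for a bacterial type, with a taxonomy string each. The tool that formed the OTUs is not given in the sources used here. Gene symbols were taken from a table of IDs and symbols, in which 17560 of 17698 gene IDs had a match. Reads outside genes (3.35% to 6.74% of a library), ambiguous reads (1.04% to 1.37%) and reads that did not align uniquely (4.66% to 10.34%) stayed out of library sizes and tests.

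Labels conflicted in places. The first recurrent library of each genotype carries a second label that gives its diet as restricted. Both lay nearest to their own title's group, at a distance of 0.586 for the control and 0.443 for the tumour library, against 0.857 and 0.795 for the restricted group, so the titles were used and the other reading was run as an alternative. Titles of 4 normal-medium libraries are used by 2 libraries each, told apart here by the letters a and b and counted as separate pools. Whether a pair repeats 1 pool was not tested, and n = 5 on normal medium would then be too high. The start of the recurrent cycle is not stated in the labels.

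Counts were analysed with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter and all 30 libraries in a single quasi-likelihood fit, and 9736 genes were tested. Genes with an adjusted p under 0.05 (Benjamini-Hochberg) were called. Log2 fold changes are given ± SE, and CPM values as means ± SD over 5 libraries. The 11 contrasts compared genotypes within each diet, diets within each genotype, and the diet effects between genotypes. Gene lists, comparisons, tests and the rule for naming genes were fixed before the data were examined. Of 32 lists 30 had tested genes; the mitochondrially encoded and the testis lists had 0. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry. Named genes were the 6 largest changes each way among called genes with a mean log2 CPM of at least 3, with CG numbers only among the first 3, and up to 2 list members each way with the smallest p. The text keeps a selection of these. The size of the tumour difference was compared between diets on genes selected in the third, with fry; adjustment over the 3 selections was added after the results were seen. The diet effects of control and tumour flies that were correlated share no libraries.

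For 16S, 16 chloroplast OTUs (2462 reads) and 4 Wolbachia OTUs (596035 reads) were left out of the community, and samples were rarefied to 2591 reads. Bray-Curtis distances were tested with vegan 2.7.1 by 9999 permutations within strata, and the Shannon index by permutation tests with 100000 resamples, 2-sided. Genera with at least 10 reads in at least 5 samples (92 of 301) were tested with edgeR, with 1 coefficient per group as planned. Because a group without reads leaves an average over groups without a usable test, a model with strata and a single term was added after the results were seen. Shares of listed families and genera were compared by exact permutation tests, 2-sided, between 22 pairs of groups. Of the listed taxa Leuconostocaceae, Gluconobacter, Commensalibacter, Leuconostoc, Providencia, Serratia and Ralstonia had no reads.

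The RNA test was checked on simulated counts for tumour against control on normal medium, over 9613 genes: it called 63.6% of 66 genes changed 1.5-fold, 82.1% of 67 changed 2-fold, 91% of 67 changed 4-fold and 0.06% of 9414 unchanged genes. The genus test called 10 of 10 genera raised 8-fold and 1 of 81 others when no group was empty, and with an empty group per genus 8 of 10 and 57 others. Alternatives were other scalings, filters, tools (DESeq2 1.42.0), replicate blocks, label readings, each library left out in turn and covariates for neighbouring tissue. The depth allowed a 2-fold change to be called in most simulated cases, and p-values and intervals cover the spread between pools and counting error only. Values were also handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plotted with matplotlib 3.10.9.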

Results

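RNA-seq of the adult Drosophila melanogaster midgut was carried out on 30 libraries that crossed 2 genotypes with 3 diets, with 5 libraries in each of the 6 groups, all collected at 13 days. Tumour flies expressed a gain-of-function form of the kinase Raf under the esg-Gal4 driver, which is active in intestinal stem and progenitor cells, and control flies came from the same driver line crossed to a strain without the Raf transgene. Flies were raised at 20 °C and moved to 29 °C at 5 to 7 days after eclosion, which releases the driver from its temperature-sensitive repressor Gal80. Normal medium (NM) contained 2% yeast, the restricted diet (DR) contained 0.1% yeast, and the recurrent diet (DRNM) alternated 4 days of restriction with 3 days of normal medium. Each library came from a pool of 15 midguts and held between 15.3 and 26.5 × 10⁶ reads assigned to genes (median 20.6 × 10⁶). Gut bacteria were measured by 16S rRNA gene sequencing in 80 pools of 5 midguts, in 16 groups of 5, with normal medium and restriction at 3, 6 and 10 days and the recurrent diet at 6 and 10 days. The 16S samples held between 2593 and 70278 reads. The labels do not say whether the pools of a group came from separate crosses or vials, so p-values measure the spread between these pools, which may be technical.

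The genotype labels were checked first. The Raf gene lay at 31 ± 1.64 counts per 10⁶ (CPM; mean ± SD, n = 5) in control flies and 29.9 ± 3.16 CPM in tumour flies on normal medium, and the log2 difference of -0.05 ± 0.096 (± SE) did not pass the test, nor did those on the restricted diet (-0.18 ± 0.096) and the recurrent diet (-0.23 ± 0.096). Counts of this gene therefore did not separate the genotypes. The driver gene esg was not analysed here. The gene w, an eye pigment transporter whose mini-gene marks many fly transgenes, did separate them. Its group means lay between 186 and 226 CPM in tumour flies and between 67.6 and 90.7 CPM in control flies. In single libraries it lay between 179.61 and 264.7 CPM in tumour and between 64.38 and 95.68 CPM in control flies, so w put every library with the genotype of its title, including 4 normal-medium libraries whose library numbers lie in the run of the other genotype. It was higher in tumour flies by 1.30 ± 0.078 on normal medium, 1.46 ± 0.078 on the restricted diet and 1.45 ± 0.078 on the recurrent diet, on the log2 scale. Transcripts of neighbouring tissue varied between libraries of one group. The hindgut regulator byn ranged from 0.203 to 41.1 CPM over the 30 libraries, with group means between 1.87 ± 1.28 CPM in restricted tumour flies and 19.8 ± 3.96 CPM in control flies on normal medium, and the renal tubule enzyme gene Uro ranged from 0.7 to 466.4 CPM.

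**Figure D1:**
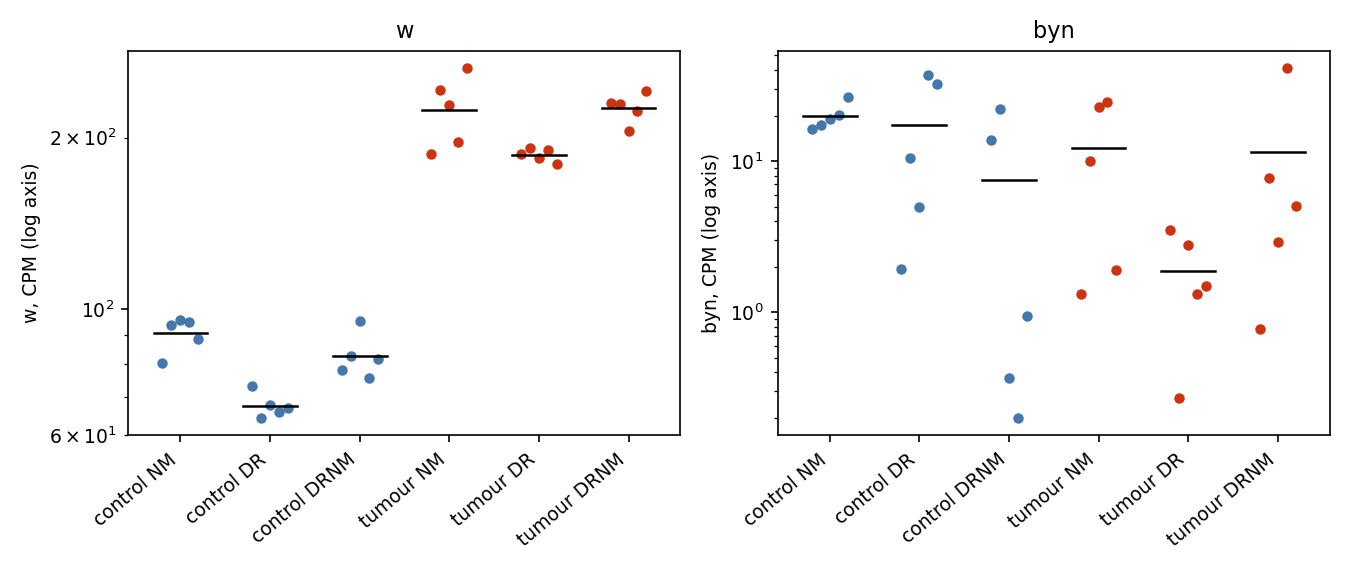
Levels of w (left) and of the hindgut gene byn (right) in CPM on a log axis, 1 point per library and 5 libraries per group, with a line at each group mean. The tumour groups have mean w levels of 186 to 226 CPM against 67.6 to 90.7 CPM in the control groups, whereas byn spreads from 0.203 to 41.1 CPM and varies within groups of both genotypes.

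On normal medium, midguts of tumour flies had more transcripts of cell division, of the JAK-STAT ligand upd1 and of the metalloprotease Mmp2, and fewer transcripts of enteroendocrine hormones, respiratory chain subunits and proton pump subunits than control midguts. This comparison asks how tumour midguts differ from control midguts when flies are fully fed. The genotypes came from crosses to different strains, and in the 16S pools a Wolbachia infection followed genotype, so differences in expression cannot be assigned to the Raf transgene alone on any diet. In all, 2963 of 9736 tested genes differed at an adjusted p under 0.05 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), 1462 higher and 1501 lower. Of the 30 tested genes of mitosis and DNA replication, 25 rose and 0 fell (26 rose when adjusted over the list alone), with a median log2 change of 0.68. Examples were Incenp (0.97 ± 0.13) and BubR1 (0.91 ± 0.10), which act in chromosome segregation. The list was called by camera (adjusted p = 6.18e-14), and adjusted p = 0.0945 with an estimated correlation. Of 11 progenitor genes, 7 rose and 1 fell (8 and 1 adjusted over the list alone), among them the Notch targets E(spl)m3-HLH (1.14 ± 0.16) and E(spl)mbeta-HLH (0.75 ± 0.14), while the stem cell gene mira (-0.38 ± 0.14) fell. The camera adjusted p was 0.000398, and the adjusted p was 0.0945 with an estimated correlation. Of 17 genes of the EGFR and Ras-MAPK pathway, 8 rose and 1 fell, in the same numbers when adjusted over the list alone. The feedback inhibitor sty (1.62 ± 0.13) and the ligand spi (0.64 ± 0.066) rose, and rl (-0.57 ± 0.078), which encodes ERK, fell. In camera the adjusted p was 0.00162, and the adjusted p was 0.215 with an estimated correlation. The JAK-STAT ligand upd1 (4.50 ± 0.35) increased from 0.745 ± 0.265 to 16.9 ± 4.78 CPM, and its receptor dome (0.69 ± 0.14) and the matrix metalloprotease Mmp2 (2.08 ± 0.25) rose.

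Other cell types of the gut moved as well on normal medium. Of 17 enteroendocrine genes 12 fell and 1 rose (the same numbers adjusted over the list alone), with a median of -1.01. The hormone genes Tk (-2.01 ± 0.18), Orcokinin (-2.63 ± 0.20) and NPF (-3.25 ± 0.30) fell, whereas ITP (1.03 ± 0.11), an ion transport peptide, rose. By camera the adjusted p was 1.33e-08, and the adjusted p was 0.0945 with an estimated correlation. Haemocyte markers were higher for 6 of 8 tested genes (7 adjusted over the list alone), led by Hml (4.80 ± 0.42) and Sr-CI (1.38 ± 0.21). Visceral muscle markers were higher for 12 of 12, such as Prm (0.87 ± 0.15) and Act57B (0.78 ± 0.15). With camera the adjusted p was 3.66e-05 for haemocytes and 8.25e-06 for muscle, and with an estimated correlation the adjusted p was 0.0945 and 0.176. Respiratory chain subunits fell in 37 of 66 genes (41 adjusted over the list alone), for example ATPsynbeta (-0.39 ± 0.068), and V-ATPase subunits fell in 15 of 22 and rose in 3 (16 and 3 adjusted over the list alone). Examples were Vha100-4 (-2.31 ± 0.25) and VhaAC39-1 (-0.68 ± 0.068) lower and VhaM9.7-a (1.45 ± 0.25) higher. Their camera adjusted p was 4.94e-10 and 8.46e-06, and with an estimated correlation the adjusted p was 0.42 and 0.0945. Digestive serine proteases fell in 9 of 29 genes and rose in 2 (10 and 3 adjusted over the list alone), with Jon99Ciii (-3.63 ± 0.52) and Jon25Biii (-2.51 ± 0.36) lower and Jon25Bi (2.09 ± 0.39) higher, and the gastric lipase gene mag (-2.60 ± 0.33) fell (protease list, camera adjusted p = 0.0318, and adjusted p = 0.635 with an estimated correlation). Antimicrobial genes DptA (3.48 ± 0.67), Def (2.63 ± 0.71) and Drsl3 (2.53 ± 0.46) rose, and the amidase gene PGRP-SC2 (-2.48 ± 0.27) fell; 9 of 25 genes of this list rose and 2 fell (11 and 2 adjusted over the list alone; camera adjusted p = 0.0263, and adjusted p = 0.502 with an estimated correlation). The largest changes in well-expressed genes also included the mannosidase LManVI (3.58 ± 0.61), CG14302 (3.54 ± 0.35) and the RNA regulator Marf1 (3.15 ± 0.24) among those that rose, and the kinase p38c (-4.85 ± 0.14), CG12057 (-4.08 ± 0.66) and the yolk protein gene Yp1 (-3.12 ± 0.90) among those that fell. Without the 4 normal-medium libraries numbered in the run of the other genotype, 1890 genes passed.

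On the restricted diet the difference between tumour and control midguts covered more genes: 3414 higher and 3063 lower in tumour flies (edgeR quasi-likelihood test). Division genes and heat shock genes were higher, and ribosomal proteins, respiratory chain subunits, digestive proteases and carbohydrases were lower. This comparison asks whether tumours still differ from normal tissue when yeast is scarce. Each of the 30 tested mitosis and replication genes rose, with a median of 1.85, including BubR1 (1.81 ± 0.10) and RnrS (1.58 ± 0.10), a subunit of ribonucleotide reductase. Of 13 heat shock genes 12 rose, with a median of 2.88, among them Hsp26 (3.98 ± 0.23) and Hsp70Bb (2.42 ± 0.14). The counts were the same when adjusted over the list alone. The camera adjusted p was 1.2e-12 and 1.93e-05, and with an estimated correlation the adjusted p was 0.118 for both. Of 83 cytosolic ribosomal protein genes 80 fell, with a median of -0.68, such as RpL22 (-0.91 ± 0.061) and RpS2 (-1.15 ± 0.094). Similarly 16 of 17 ribosome biogenesis genes fell, such as nop5 (-0.91 ± 0.065) and Polr1A (-0.79 ± 0.069), with the same counts adjusted over the list alone. Their camera adjusted p was 4.21e-14 and 5.54e-08, and with an estimated correlation the adjusted p was 0.413 and 0.102. Respiratory chain subunits fell in 64 of 66 genes, including SdhA (-1.11 ± 0.070) and ATPsynbeta (-1.18 ± 0.069). Tested with camera, the adjusted p was 1.71e-14, and the adjusted p was 0.3 with an estimated correlation.

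Most digestive enzyme genes were lower in tumour flies on this diet. Of 29 serine proteases 25 fell and 1 rose, with a median of -1.74: zetaTry (-6.18 ± 0.37), Jon65Aii (-6.17 ± 0.51) and Jon25Biii (-6.01 ± 0.42) fell and Jon66Ci (2.42 ± 0.47) rose. Of 20 carbohydrases 17 fell (18 adjusted over the list alone), such as the maltases Mal-A3 (-3.47 ± 0.23) and Mal-A2 (-1.67 ± 0.11). In camera the adjusted p was 5.54e-08 and 3.39e-07, and with an estimated correlation the adjusted p was 0.249 and 0.144. The lipase gene mag (-6.88 ± 0.41) and the uncharacterised genes CG5770 (-7.71 ± 0.52) and CG9682 (-6.76 ± 0.57) fell. Autophagy genes rose in 15 of 18, with Atg14 (1.12 ± 0.079) and Atg8a (0.96 ± 0.071). The adjusted p from camera was 0.000518, and the adjusted p was 0.118 with an estimated correlation. Signalling genes higher in tumour flies included Mmp2 (4.45 ± 0.28), the insulin-binding protein gene ImpL2 (3.90 ± 0.23), sty (2.09 ± 0.13), spi (1.02 ± 0.066), upd1 (5.12 ± 0.39), the progenitor factor Sox21a (2.22 ± 0.18) and the asparagine synthetase AsnS (1.56 ± 0.099). JNK and matrix genes rose in 11 of 12. Camera gave an adjusted p of 0.000717, and the adjusted p was 0.102 with an estimated correlation. The septate junction genes Ssk (1.62 ± 0.12) and Tsp2A (1.55 ± 0.13) rose while the transcription factors GATAe (-0.84 ± 0.12) and cad (-1.64 ± 0.21) fell, all from the enterocyte list, which camera did not call (adjusted p = 0.55). The hormone gene Tk (-2.68 ± 0.18) fell and ITP (2.62 ± 0.12) rose, with 13 of 17 enteroendocrine genes lower. The camera adjusted p was 0.000269, and the adjusted p was 0.249 with an estimated correlation. The antimicrobial gene DptA stood at 133 ± 42.5 CPM in tumour flies and 0.303 ± 0.119 CPM in control flies. Other large increases were cGlr1 (4.02 ± 0.34), CG4250 (4.12 ± 0.29) and the lysozyme LysX (3.74 ± 0.45). Hindgut and fat body transcripts moved with this contrast too: byn averaged 1.87 ± 1.28 CPM in tumour and 17.4 ± 16.3 CPM in control flies, and 6 of 6 fat body genes fell, led by Yp1 (-6.17 ± 1.16) (fat body list, camera adjusted p = 0.125).

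On the recurrent diet 3824 genes differed between tumour and control midguts, 1856 higher and 1968 lower (edgeR quasi-likelihood test). Division, heat shock and progenitor genes were again higher, and enteroendocrine genes and digestive proteases lower. Of 30 mitosis and replication genes 27 rose, with a median of 1.1, including BubR1 (1.11 ± 0.10) and RnrS (1.01 ± 0.10). Of 13 heat shock genes 12 rose, including Hsp26 (2.71 ± 0.21) and Hsp70Bb (2.02 ± 0.14), and 9 of 11 progenitor genes rose, including E(spl)m3-HLH (1.42 ± 0.16) and zfh2 (1.14 ± 0.16), with mira (-1.10 ± 0.14) lower. The counts were the same adjusted over each list alone. By camera the adjusted p was 2.26e-17, 5.45e-07 and 0.000214, and with an estimated correlation the adjusted p was 0.092 for each of these lists. Of 17 enteroendocrine genes 15 fell and 1 rose, with Tk (-2.71 ± 0.18) and Orcokinin (-2.90 ± 0.20) lower and ITP (1.60 ± 0.12) higher. In addition 7 of 8 haemocyte genes rose, led by Hml (3.24 ± 0.37) and Sr-CI (2.02 ± 0.21). In camera the adjusted p was 1.74e-09 and 3.9e-05, and the adjusted p was 0.092 with an estimated correlation. Proteases fell in 19 of 29 genes and rose in 2, with Jon99Ciii (-4.48 ± 0.54) and Jon99Cii (-4.32 ± 0.52) lower and Ser8 (1.41 ± 0.30) higher. Respiratory chain subunits fell in 36 of 66, such as UQCR-C1 (-0.44 ± 0.071). The camera adjusted p was 2.48e-06 and 8.09e-08, and with an estimated correlation the adjusted p was 0.385 and 0.576. The ligand upd1 (4.30 ± 0.36), the metalloprotease Mmp2 (2.41 ± 0.26), the EGFR feedback inhibitors sty (1.53 ± 0.13) and aos (1.51 ± 0.13), and AsnS (1.32 ± 0.098) rose. The translation repressor gene Thor (-1.26 ± 0.14), the sugar-responsive factor sug (-1.71 ± 0.20), the lipase mag (-4.38 ± 0.36), the triglyceride synthesis gene Dgat2 (-3.16 ± 0.32) and the cation channel gene TrpA1 (-4.62 ± 0.29) fell. Among the largest changes, Marf1 (3.34 ± 0.25), CG18179 (3.36 ± 0.35), MFS3 (2.69 ± 0.32), mat (3.42 ± 1.09) and Def (2.97 ± 0.75) rose, and CG17192 (-5.93 ± 0.50), p38c (-5.24 ± 0.14), Yp1 (-4.77 ± 0.97) and Yp2 (-4.94 ± 0.92) fell. With a term for the run of library numbers 2536 genes passed, and with the first recurrent library of each genotype counted as restricted, as a second label has it, 2409 passed.

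The size of the tumour difference was compared between diets on genes selected in the remaining diet, so that no library served both to select and to compare. Genes called on normal medium (2963) had a median difference, signed by the direction of selection, of 0.76 log2 units on the restricted diet and 0.60 on the recurrent diet (limma's fry with Benjamini-Hochberg adjustment over the 3 selections, adjusted p = 0.0427 for the difference between these diets). That call was lost when any 1 of 10 of the 30 libraries was left out. Genes called on the recurrent diet (3824) had a median of 0.40 on normal medium and 0.79 on the restricted diet (limma's fry, adjusted p = 2.81e-07). Genes called on the restricted diet had a median of 0.18 on normal medium and 0.28 on the recurrent diet (limma's fry, adjusted p = 0.0282). Among genes selected on the recurrent diet the tumour difference was thus larger under restriction than on normal medium. The direction was kept for 94.4% of these genes on normal medium and 87.4% on the restricted diet. Either genotype can widen the difference: under restriction most mitosis genes fell in control flies, without a common direction in tumour flies.

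**Figure D2:**
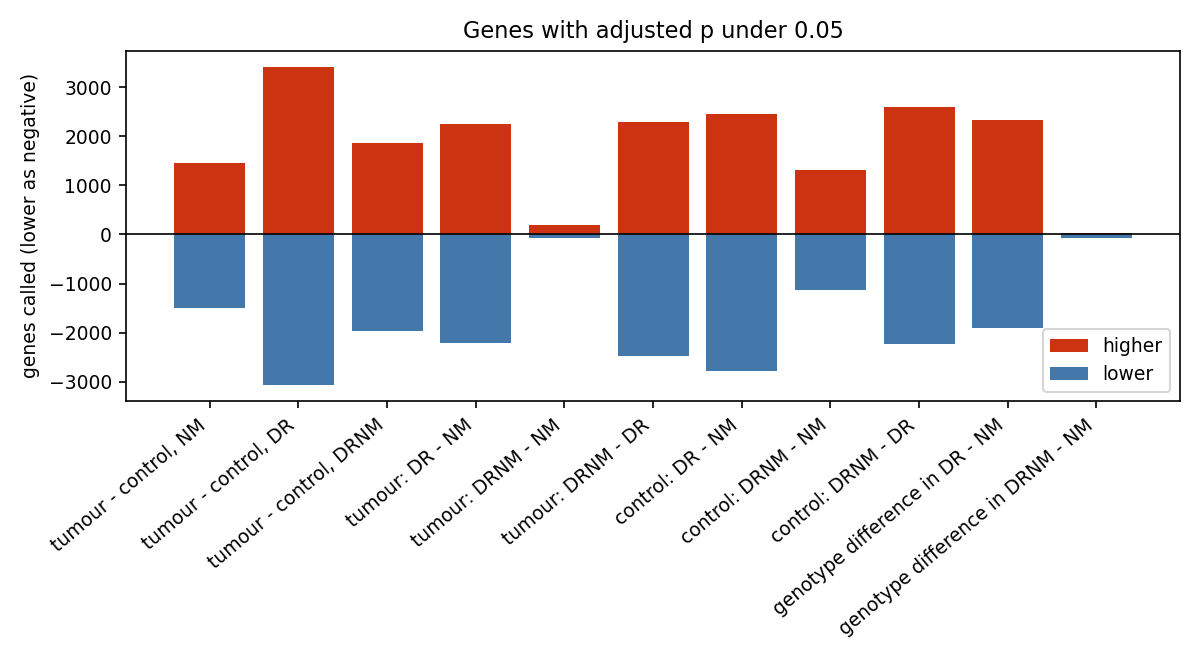
Number of genes with an adjusted p under 0.05 in each RNA-seq contrast (edgeR quasi-likelihood test), with genes higher in the first-named group above 0 and genes lower below 0. Tumour against control gives 2963 genes on normal medium, 3414 higher and 3063 lower on the restricted diet and 3824 on the recurrent diet, and recurrent against normal gives 263 genes in tumour flies and 2434 in control flies.

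In tumour flies, constant restriction lowered most tested proton pump and carbohydrase genes and raised most ribosomal protein genes. In this test of what restriction does to tumour tissue, 4476 genes differed from normal medium, 2257 higher and 2219 lower (edgeR quasi-likelihood test). Of 20 carbohydrases 11 fell and 2 rose (11 and 3 adjusted over the list alone), with Amyrel (-5.79 ± 0.31) and the maltase Mal-A4 (-2.29 ± 0.16) lower. The lipase mag (-3.60 ± 0.36) and the sterol uptake gene Npc1b (-3.48 ± 0.27) fell, and the sterol-binding protein gene Npc2c (3.85 ± 0.64) rose. Of 22 V-ATPase subunits 15 fell and 1 rose (17 and 1 adjusted over the list alone), including Vha55 (-0.70 ± 0.089) and VhaAC39-1 (-0.58 ± 0.068) among the lower ones. Camera called both lists (adjusted p = 0.0216 and 2.31e-05), and with an estimated correlation the adjusted p was 0.79 and 0.334. Of 83 ribosomal protein genes 46 rose and 1 fell (55 and 1 adjusted over the list alone), with a median of 0.31; RpL24-like (1.10 ± 0.13) rose and RpS5b (-2.46 ± 0.40) fell. By camera the adjusted p was 5.91e-06, and the adjusted p was 0.79 with an estimated correlation. Of 17 genes of insulin, TOR and starvation signals 8 rose and 2 fell (9 and 2 adjusted over the list alone). The translation repressor Thor (1.21 ± 0.14) and the TOR-regulated factor REPTOR-BP (1.09 ± 0.11) rose, and Sesn (-0.75 ± 0.16) and ImpL2 (-0.79 ± 0.20) fell. Tested with camera, the adjusted p was 0.0216, and the adjusted p was 0.334 with an estimated correlation. Glycolysis genes fell in 7 of 13, including Ldh (-1.04 ± 0.12). The adjusted p from camera was 0.00767, and the adjusted p was 0.79 with an estimated correlation.

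Mitosis and replication genes of tumour flies showed no common direction under restriction: 2 of 30 rose and 6 fell (2 and 4 adjusted over the list alone), with a median of -0.2 (camera adjusted p = 0.099). Cdk2 (0.66 ± 0.17) rose and RnrL (-0.55 ± 0.13) and Klp61F (-0.53 ± 0.13) fell. Protease genes deltaTry (-4.13 ± 0.35) and Jon66Cii (-5.21 ± 0.49) fell and Jon99Ciii (1.35 ± 0.49) and Jon74E (1.12 ± 0.33) rose, with 13 of 29 lower and 4 higher (camera adjusted p = 0.101). The autophagy genes Atg8a (0.98 ± 0.071) and Atg101 (0.89 ± 0.12), the stem cell gene mira (1.16 ± 0.14), the heat shock gene Hsp26 (1.00 ± 0.20), the transcription factor chinmo (2.36 ± 0.26), the TNF ligand egr (0.85 ± 0.099) and the signal hh (2.35 ± 0.23) rose. The immune regulators pirk (-1.84 ± 0.28) and Rel (-0.64 ± 0.13), the stress gene TotM (-4.95 ± 0.89) and the growth factor vn (-0.64 ± 0.21) fell. Of the largest changes, CG15199 (4.79 ± 0.44), CG8745 (3.01 ± 0.41), the transporter Mdr50 (2.85 ± 0.42), Cyp6w1 (2.45 ± 0.43) and Bin1 (2.41 ± 0.20) rose, and CG33337 (-6.60 ± 0.54), CG14219 (-5.13 ± 0.25) and CG18404 (-5.07 ± 0.47) fell. The renal tubule genes Uro (-4.44 ± 0.99), salt (-4.08 ± 1.03) and Oatp58Dc (-4.11 ± 0.91) were also among the largest decreases, and byn averaged 12.1 ± 11.1 CPM on normal medium and 1.87 ± 1.28 CPM on the restricted diet. With the first recurrent library of each genotype counted as restricted, 2679 genes passed.

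The recurrent diet, by contrast, left 263 genes different from normal medium in tumour flies, 200 higher and 63 lower (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Digestive proteases and carbohydrases were among the genes that rose. Of 29 serine proteases 17 rose and 0 fell (23 rose adjusted over the list alone), with a median of 1.27, and the list was called with the preset correlation (camera adjusted p = 1.31e-36) and with the estimated one (adjusted p = 0.0261 with an estimated correlation). Examples were Jon25Biii (2.75 ± 0.36), Jon65Ai (2.81 ± 0.45), Jon99Ciii (3.06 ± 0.51), Jon99Cii (3.02 ± 0.49), Jon99Ci (2.96 ± 0.51), Jon99Fi (3.31 ± 0.68) and Jon99Fii (3.20 ± 0.57). Of 20 carbohydrases 9 rose, in the same number adjusted over the list alone, including LManIV (3.53 ± 0.62) and LManII (1.48 ± 0.27). Of 21 lipid handling genes 5 rose (9 adjusted over the list alone), including Npc2c (3.82 ± 0.64) and the lipid droplet gene Lsd-2 (0.55 ± 0.11). Their camera adjusted p was 2.3e-08 and 1.84e-06, and with an estimated correlation the adjusted p was 0.196 and 0.0588. Antimicrobial genes fell in 4 of 25 and rose in 1 (9 and 4 adjusted over the list alone), with DptB (-2.76 ± 0.65), AttD (-2.56 ± 0.63) and DptA (-2.38 ± 0.63) lower and PGRP-SC2 (2.34 ± 0.27) higher. Camera gave an adjusted p of 0.00357, and the adjusted p was 0.647 with an estimated correlation. The mitosis and replication list had a median of -0.1. The camera adjusted p was 0.00857, and the adjusted p was 0.773 with an estimated correlation. Other large changes were an increase of CG12057 (3.65 ± 0.65) and decreases of CG5070 (-2.49 ± 0.64), hdly (-0.72 ± 0.18) and hoe1 (-0.71 ± 0.18). This count rested on few libraries: it was 91 without recurrent replicate 3, 103 without normal-medium replicate 4b, 120 without normal-medium replicate 5, 118 when only these 10 libraries were fitted, and 35 with the first recurrent library counted as restricted.

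Recurrent against constant restriction in tumour flies gave 4760 genes, 2278 higher and 2482 lower on the recurrent diet (edgeR quasi-likelihood test). Most proteases, carbohydrases and V-ATPase subunits were higher, and most ribosomal protein genes and genes of insulin, TOR and starvation signals lower. Of 29 proteases 27 rose, with a median of 1.78, led by Jon66Cii (6.47 ± 0.51), deltaTry (4.49 ± 0.35) and Jon25Biii (3.93 ± 0.38). Of 20 carbohydrases 14 rose and 1 fell (15 and 1 adjusted over the list alone), with Amyrel (6.76 ± 0.32) and Mal-A4 (2.34 ± 0.16) higher. Of 22 V-ATPase subunits 18 rose and 1 fell (18 and 2 adjusted over the list alone), with Vha55 (0.95 ± 0.089) higher. Tested with camera, the adjusted p was 4.98e-12, 3.48e-06 and 3.39e-07, and with an estimated correlation the adjusted p was 0.436, 0.436 and 0.148. Respiratory chain subunits rose in 29 of 66 genes and fell in 0, with the same counts adjusted over the list alone (camera adjusted p = 9.6e-07, and adjusted p = 0.714 with an estimated correlation). The lipid genes mag (4.55 ± 0.37) and Npc1b (3.31 ± 0.27), the glycolysis genes Ldh (1.33 ± 0.12) and Hex-A (1.19 ± 0.15), the succinate dehydrogenase subunit SdhA (0.85 ± 0.069), and TotM (5.39 ± 0.88) rose. Of 83 ribosomal protein genes 59 fell (72 adjusted over the list alone), with a median of -0.36. Of 17 starvation and insulin signals 10 fell and 2 rose, with Thor (-1.43 ± 0.14) and REPTOR-BP (-1.34 ± 0.11) lower. In camera the adjusted p was 1.43e-07 and 0.0437, and with an estimated correlation the adjusted p was 0.714 and 0.436. The autophagy gene Atg8a (-0.95 ± 0.071), Hsp26 (-1.12 ± 0.20), mira (-1.09 ± 0.14), chinmo (-2.30 ± 0.26), the metal-binding protein gene MtnA (-2.11 ± 0.28) and DptB (-2.77 ± 0.65) fell. So did Bin1 (-2.44 ± 0.20), CG8745 (-2.95 ± 0.41) and CG14302 (-2.53 ± 0.32), while CG33337 (5.86 ± 0.53), CG9682 (5.16 ± 0.54) and Diedel3 (4.33 ± 0.55) rose. Renal tubule and hindgut transcripts were higher on the recurrent diet, with Uro (3.14 ± 0.95) and a byn mean of 11.5 ± 16.7 CPM. With the first recurrent library counted as restricted 2675 genes passed.

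In control flies, constant restriction raised ribosomal protein and ribosome biogenesis genes and lowered mitosis and replication genes. In all, 5219 genes differed from normal medium, 2441 higher and 2778 lower (edgeR quasi-likelihood test). Of 83 ribosomal protein genes 82 rose, with a median of 0.96, such as RpL22 (1.05 ± 0.061) and RpL3 (1.01 ± 0.072). Likewise 17 of 17 ribosome biogenesis genes rose, such as nop5 (1.14 ± 0.065) and Nop60B (1.00 ± 0.062). The counts were the same over each list alone. The adjusted p from camera was 5.43e-30 and 2.56e-13, and with an estimated correlation the adjusted p was 0.384 for ribosomal proteins and 0.0315 for ribosome biogenesis. Of 30 mitosis and replication genes 28 fell, with a median of -1.35, including RnrL (-1.76 ± 0.14) and BubR1 (-1.28 ± 0.10). In camera the adjusted p was 5.33e-11, and the adjusted p was 0.313 with an estimated correlation. JAK-STAT genes fell in 8 of 11 (9 adjusted over the list alone), including the ligand upd3 (-2.86 ± 0.30) and the receptor dome (-1.21 ± 0.14). JNK and matrix genes fell in 8 of 12, including Mmp2 (-1.79 ± 0.26) and Mmp1 (-0.71 ± 0.097), whereas chinmo (1.48 ± 0.26) and egr (0.76 ± 0.10) rose. Their camera adjusted p was 0.0292 and 0.0325, and with an estimated correlation the adjusted p was 0.313 for both. Of 18 autophagy genes 11 fell and 1 rose (11 and 2 adjusted over the list alone), with ref(2)P (-0.96 ± 0.083) and Atg18a (-0.72 ± 0.065) lower and Atg10 (0.49 ± 0.20) higher. Heat shock genes fell in 8 of 13 (9 adjusted over the list alone), including Hsp27 (-1.84 ± 0.20). By camera the adjusted p was 0.0121 and 0.0079, and with an estimated correlation the adjusted p was 0.371 and 0.388.

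Digestive genes of restricted control flies moved both ways. Of 29 proteases 19 rose and 5 fell, with Jon99Fii (4.85 ± 0.61), zetaTry (4.68 ± 0.34) and Jon65Aii (4.48 ± 0.47) higher and Jon66Cii (-5.92 ± 0.55) and Jon66Ci (-3.65 ± 0.49) lower. By camera the adjusted p was 0.000236, and the adjusted p was 0.74 with an estimated correlation. Of 20 carbohydrases 8 rose and 7 fell (camera adjusted p = 0.691; median -0.25, mean 1.61), as the mannosidases rose while Amyrel (-2.33 ± 0.25) and Mal-A6 (-1.69 ± 0.13) fell. LManVI went from 7.83 ± 3.66 to 2161 ± 680 CPM (8.11 ± 0.75), LManV from 1.2 ± 0.487 to 864 ± 332 CPM, and LManIII from 0.234 ± 0.262 to 287 ± 115 CPM. The insulin-binding protein gene ImpL2 (-4.37 ± 0.23), the EGFR activator rho (-3.39 ± 0.25), Sox21a (-1.46 ± 0.18), the sterol uptake gene Npc1b (-3.69 ± 0.27), the glutathione transferase GstD5 (-2.65 ± 0.19) and the lysozyme LysX (-5.80 ± 0.49) fell. Transcripts of foxo (1.07 ± 0.15), S6k (0.80 ± 0.10), mira (1.21 ± 0.14), Dgat2 (2.00 ± 0.30) and MtnA (5.26 ± 0.32) rose. Antimicrobial and recognition genes fell in 17 of 25 and rose in 4, with a median of -2.36 (camera adjusted p = 0.284); DptB went from 12 ± 10.2 to 0.0225 ± 0.031 CPM, and PGRP-SC1b (3.85 ± 0.45) rose. Large decreases were also seen for Agpat1 (-3.89 ± 0.23), CG33337 (-4.58 ± 0.48), CG7298 (-4.70 ± 0.53) and the yolk protein gene Yp2 (-4.04 ± 0.90). Visceral muscle genes rose in 7 of 12, such as Tm2 (0.47 ± 0.10) (camera adjusted p = 0.0348, and adjusted p = 0.74 with an estimated correlation), and Uro (-3.15 ± 0.94) fell.

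On the recurrent diet, 2434 genes of control flies differed from normal medium, 1307 higher and 1127 lower (edgeR quasi-likelihood test). Of 29 proteases 24 rose (25 adjusted over the list alone), with a median of 2.06, led by Jon99Fi (5.16 ± 0.74), Jon99Fii (4.56 ± 0.60), Jon25Bii (4.36 ± 0.45), Jon99Ciii (3.91 ± 0.52) and zetaTry (3.24 ± 0.32). Lipid handling genes rose in 11 of 21 and fell in 1 (12 and 1 adjusted over the list alone), with the acyl-CoA synthetase bgm (1.70 ± 0.15) and Lsd-2 (1.49 ± 0.11) higher and FASN2 (-1.04 ± 0.31) lower. Both lists were called by camera (adjusted p = 1.14e-24 and 4.43e-06), and with an estimated correlation the adjusted p was 0.0771 for both. Mitosis and replication genes fell in 16 of 30 (25 adjusted over the list alone), including polo (-0.70 ± 0.15) and RnrS (-0.62 ± 0.10). Heat shock genes fell in 7 of 13 (10 adjusted over the list alone), including Hsp83 (-1.59 ± 0.38) and Hsp26 (-1.30 ± 0.21). Tested with camera, the adjusted p was 2.42e-09 and 0.000216, and with an estimated correlation the adjusted p was 0.359 and 0.313. Ribosomal protein genes rose in 13 of 83 (11 adjusted over the list alone), with a median of 0.22. Visceral muscle genes rose in 8 of 12, such as Act57B (0.95 ± 0.15). The adjusted p from camera was 3.51e-06 and 0.000703, and with an estimated correlation the adjusted p was 0.947 and 0.583. Transcripts of foxo (0.92 ± 0.15), sug (1.22 ± 0.20), mira (0.79 ± 0.14), PGRP-SC1b (3.37 ± 0.45), LManVI (3.88 ± 0.62) and CG12374 (4.53 ± 0.47) rose. DptA (-4.61 ± 0.82), TotM (-3.55 ± 0.70), rho (-1.02 ± 0.23), GstD2 (-1.67 ± 0.27), IM33 (-2.02 ± 0.57), CG31106 (-1.94 ± 0.62), ana (-2.13 ± 0.39), eys (-1.93 ± 0.30) and yellow-b (-1.60 ± 0.50) fell. Hindgut transcripts moved with this contrast: byn averaged 19.8 ± 3.96 CPM on normal medium and 7.49 ± 10 CPM on the recurrent diet, where replicates 1 and 2 (13.83 and 22.12 CPM) stood apart from the others (0.2 to 0.95 CPM). With the hindgut genes as a covariate 3081 genes passed, 2009 of them shared. With the first recurrent library counted as restricted 953 genes passed.

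Against constant restriction, the recurrent diet of control flies went with lower ribosomal and higher mitosis and autophagy transcripts. The test called 4825 genes, 2595 higher and 2230 lower (edgeR quasi-likelihood test). Ribosomal protein genes fell in 82 of 83, with a median of -0.75, including RpL22 (-0.63 ± 0.060), and ribosome biogenesis genes in 16 of 17, including nop5 (-1.17 ± 0.065) and Nop60B (-1.01 ± 0.062). Camera gave an adjusted p of 4.23e-26 and 4.59e-15, and with an estimated correlation the adjusted p was 0.488 for ribosomal proteins and 0.0173 for ribosome biogenesis. Mitosis and replication genes rose in 23 of 30 and fell in 2, with CycE (2.00 ± 0.21) and RnrL (1.17 ± 0.14) higher and Cdk2 (-0.62 ± 0.18) lower. Autophagy genes rose in 13 of 18 and fell in 1, with ref(2)P (1.10 ± 0.083) and Atg18a (0.88 ± 0.065) higher. The counts were the same adjusted over each list alone, the camera adjusted p was 1.58e-05 and 0.000304, and with an estimated correlation the adjusted p was 0.561 and 0.195. The insulin-binding protein gene ImpL2 (3.59 ± 0.23), the sterol uptake gene Npc1b (3.71 ± 0.27), the acetyl-CoA synthase AcCoAS (1.08 ± 0.090), dome (1.40 ± 0.14), Stat92E (0.93 ± 0.093), rho (2.37 ± 0.24), Sox21a (1.11 ± 0.18), Delta (0.87 ± 0.19), LysX (4.44 ± 0.46), mesh (1.18 ± 0.12), Jon66Cii (6.86 ± 0.56) and Jon66Ci (5.22 ± 0.53) rose. MtnA (-4.71 ± 0.31), LManIII (-5.78 ± 0.72), LManV (-4.50 ± 0.74), LManVI (-4.23 ± 0.62), ninaD (-3.66 ± 0.59) and Acsx3 (-2.60 ± 0.72) fell. The yolk protein gene Yp2 (5.00 ± 0.93), CG33337 (4.92 ± 0.49) and Uro (3.02 ± 0.93) were also higher. The rise of Uro and Yp2 came mostly from recurrent replicates 1 and 2, with Uro at 176.6 and 285.3 CPM (13.2 to 29.1 in the others) and Yp2 at 388.01 and 340.32 CPM (3.63 to 85.56). Hindgut transcripts moved too, as byn averaged 17.4 ± 16.3 CPM under restriction and 7.49 ± 10 CPM on the recurrent diet, and with the hindgut genes as a covariate 5087 genes passed, 4412 of them shared. With the first recurrent library counted as restricted 3060 genes passed.

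The response to constant restriction differed between the genotypes. A test of this difference called 4226 genes, 2332 with a higher and 1894 with a lower response in tumour flies (edgeR quasi-likelihood interaction test). Mitosis and replication genes had a higher response in 24 of 30 (25 adjusted over the list alone), with a median difference of 1.13, including PCNA (2.17 ± 0.28) and Mcm5 (1.87 ± 0.24), which act at the replication fork. Heat shock genes had a higher response in 9 of 13, including Hsp27 (2.56 ± 0.28), and autophagy genes in 12 of 18 with 1 lower (13 and 1 adjusted over the list alone), including Atg14 (1.14 ± 0.11) and Atg8a (0.98 ± 0.10). The camera adjusted p was 5.32e-11, 0.00015 and 0.000124, and with an estimated correlation the adjusted p was 0.162, 0.136 and 0.106. Ribosomal proteins had a lower response in 77 of 83 genes (81 adjusted over the list alone), including RpL22 (-0.89 ± 0.085) and RpS2 (-1.17 ± 0.13), and ribosome biogenesis in 16 of 17, including nop5 (-1.27 ± 0.091) and Nop60B (-1.07 ± 0.086). Their camera adjusted p was 3.78e-17 and 2.88e-14, and with an estimated correlation the adjusted p was 0.425 for ribosomal proteins and 0.0225 for ribosome biogenesis. Digestive proteases had a lower response in 23 of 29 genes and a higher one in 1, with zetaTry (-6.21 ± 0.47) and Jon25Biii (-3.50 ± 0.49) lower. Respiratory chain subunits had a lower response in 36 of 66 (37 adjusted over the list alone), with SdhA (-0.82 ± 0.098) and ATPsynbeta (-0.80 ± 0.097) lower. Camera gave an adjusted p of 5.63e-08 and 9.38e-09, and with an estimated correlation the adjusted p was 0.35 and 0.45. ImpL2 (3.58 ± 0.30), rho (3.27 ± 0.33), Mmp2 (2.37 ± 0.35), upd3 (2.17 ± 0.40), Thor (1.19 ± 0.19), GstD5 (3.22 ± 0.26), Sox21a (1.42 ± 0.25), DptA (5.24 ± 1.14), CG4250 (4.25 ± 0.38) and CG6933 (5.02 ± 0.69) had higher responses in tumour flies. LManVI (-7.91 ± 0.87), LManV (-7.83 ± 1.09), mag (-4.28 ± 0.47), bgm (-2.76 ± 0.21), Amyrel (-3.46 ± 0.39), Diedel3 (-4.92 ± 0.72), MFS12 (-4.68 ± 0.91) and CG9682 (-6.82 ± 0.70) had lower ones. Visceral muscle markers had a lower response in 7 of 12 genes (10 adjusted over the list alone; camera adjusted p = 0.00338, and adjusted p = 0.426 with an estimated correlation). With the mean level of the hindgut genes byn and otp as a covariate, an alternative added after the data were seen, 4465 genes passed, 4161 of them shared. With the first recurrent library of each genotype counted as restricted 2776 passed.

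For the recurrent diet the same test called 86 genes, 20 with a higher and 66 with a lower response in tumour flies (edgeR quasi-likelihood interaction test with Benjamini-Hochberg adjustment). Amyrel (1.68 ± 0.33), Hsp26 (1.18 ± 0.29), GstD2 (1.49 ± 0.37), GstD10 (1.13 ± 0.26), Cyp4s3 (1.11 ± 0.25) and CG4267 (1.51 ± 0.32) had higher responses. The lipoprotein receptor gene LpR1 (-1.92 ± 0.29), Lsd-2 (-0.94 ± 0.16), bgm (-1.01 ± 0.21), mag (-1.78 ± 0.44), TrpA1 (-1.78 ± 0.37), epsilonTry (-1.68 ± 0.41), RpL22 (-0.44 ± 0.085), CG5246 (-2.09 ± 0.40) and CG6403 (-2.44 ± 0.49) had lower ones. Of 13 heat shock genes 1 passed over all genes and 6 adjusted over the list alone, with a median difference of 1.07. Tested with camera, the adjusted p was 5.56e-07, and the adjusted p was 0.166 with an estimated correlation. The count was 181 without control recurrent replicate 4, 47 and 54 without control recurrent replicates 3 and 1, 50 without control normal-medium replicate 5 and 55 without tumour recurrent replicate 5. It was 13 without the 4 normal-medium libraries numbered in the run of the other genotype, 273 with the hindgut covariate and 230 with DESeq2.

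The remaining gene lists and markers of other tissues were read in the same way. On normal medium 17 of 36 genes for glutathione transferases and P450 enzymes were lower in tumour flies and 3 higher (19 and 3 adjusted over the list alone; camera adjusted p = 9.6e-06, and adjusted p = 0.0945 with an estimated correlation). In the same contrast 4 of 10 Wnt and Dpp signal genes were higher. The adjusted p from camera was 0.0318, and the adjusted p was 0.401 with an estimated correlation. Lysozyme genes had a median of 2.11 on the recurrent diet in control flies, with 5 of 7 higher. Camera gave an adjusted p of 0.0131, and the adjusted p was 0.583 with an estimated correlation. Genes of the unfolded protein response and secretion were not called in any contrast, with 7 of 13 higher and 2 lower in restricted tumour flies (camera adjusted p = 0.118). Trachea, neuron and Malpighian tubule lists were not called either, with medians of 0.3, -0.17 and -0.07 on normal medium (camera adjusted p = 0.0676, 0.646 and 0.646), and the ovary list had 1 tested gene. Over the 330 tests of 30 lists in 11 contrasts, camera called 112 with its preset correlation and 4 with the estimated one. These 4 were the proteases on the recurrent diet in tumour flies and ribosome biogenesis in 3 contrasts of restriction. Members of families with near-identical copies, such as the Hsp70, Jon99, LMan and PGRP-SC1 genes, are uncertain one by one, since reads that align to more than 1 place were not counted.

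**Figure D3:**
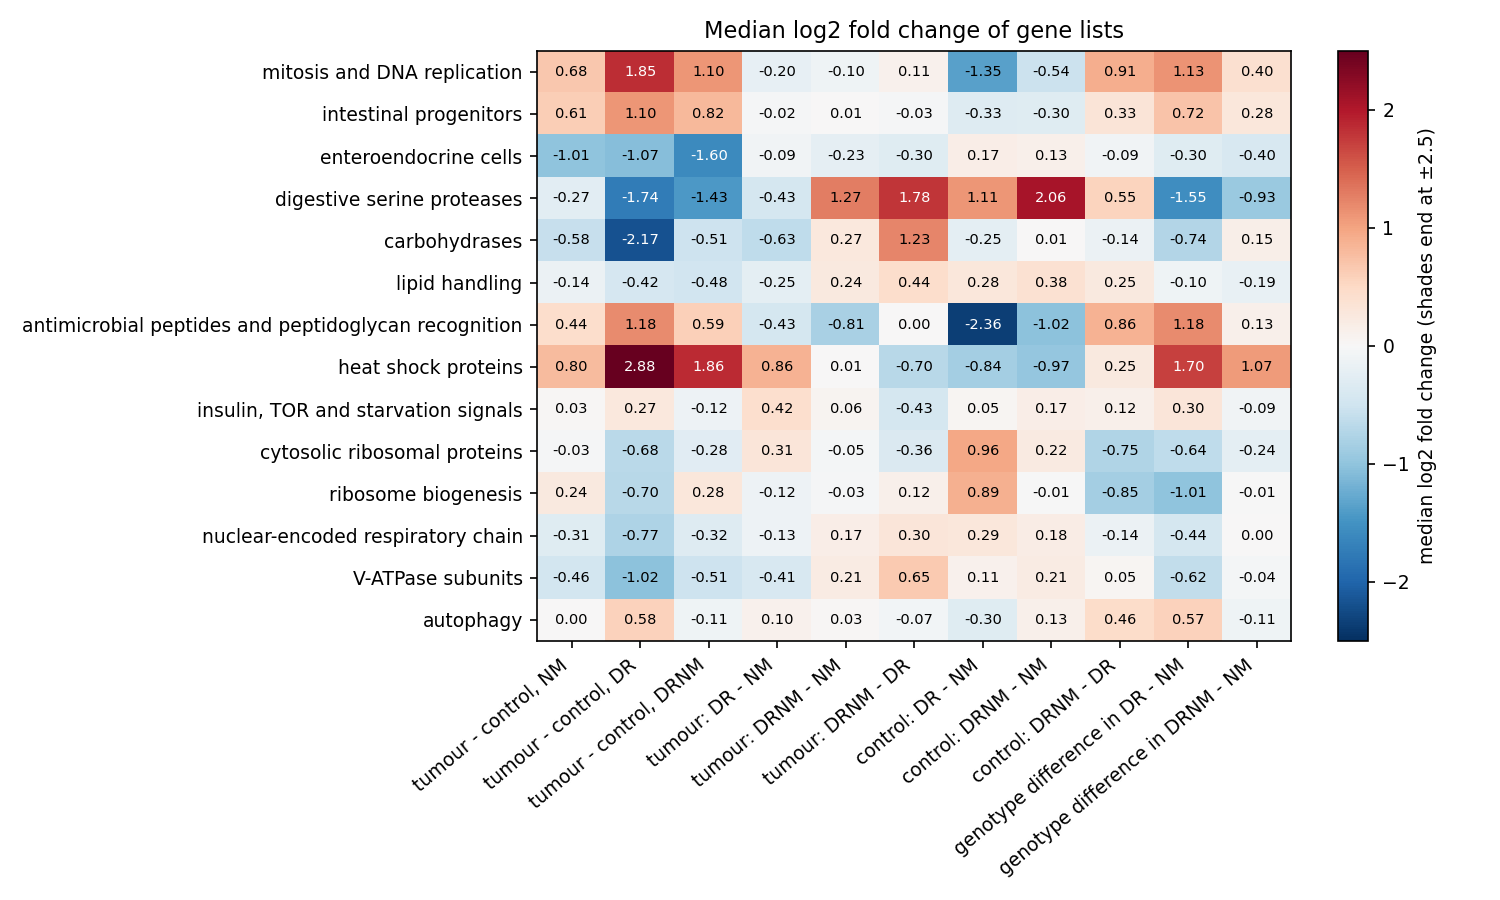
Median log2 fold change of 14 gene lists (down the grid) in the 11 RNA-seq contrasts (across), printed in each cell and shaded from blue (lower) to red (higher). The ribosomal protein list stands at 0.96 under restriction in control flies and 0.31 in tumour flies, and the mitosis list at -1.35 and -0.2.

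Across genes, the changes from normal medium to restriction in control and in tumour flies, which share no library, had a Pearson correlation of 0.41 and a Spearman correlation of 0.33 over the 9736 genes, which are not independent replicates. Both genotypes showed a rise in 882 genes against 566 for independent lists and a fall in 1050 against 633, while 641 genes moved in opposite directions against 1200. For recurrent against normal medium the Pearson correlation was 0.52, with 166 genes higher in both genotypes against 27 for independent lists and 34 lower against 7.

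**Figure D4:**
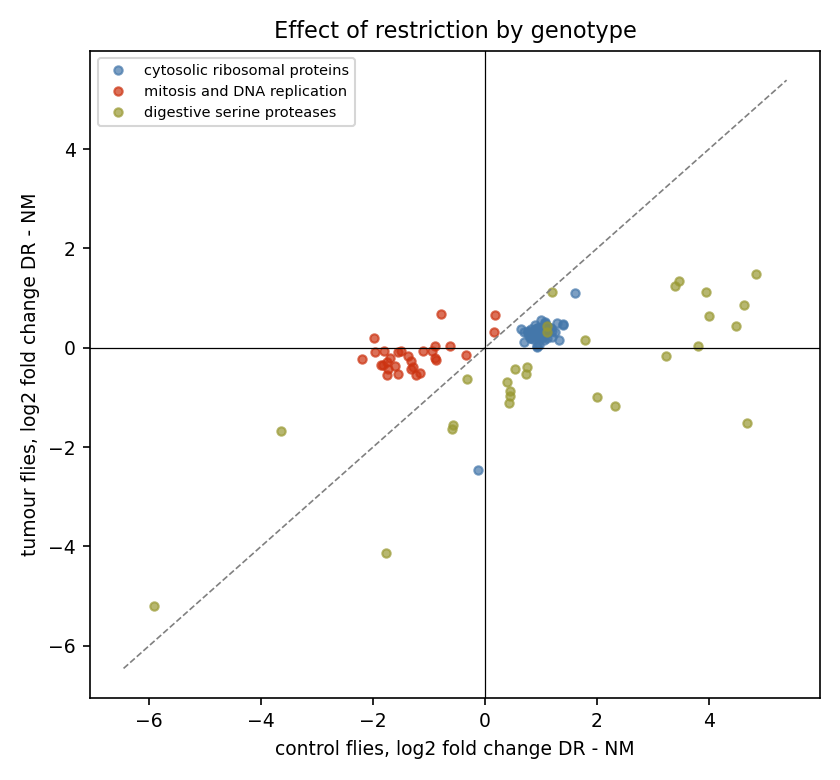
Log2 fold change from normal medium to the restricted diet in control flies (horizontal) and in tumour flies (vertical) for the tested genes of 3 lists, 1 point per gene, with lines at 0 and along equal change. Ribosomal protein genes other than RpS5b lie to the right of 0 and closer to 0 on the vertical axis, and most mitosis and replication genes lie to the left, with medians of 0.96 against 0.31 and -1.35 against -0.2.

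The bacterial community differed between genotypes and with age, and no diet contrast pooled over genotypes and days passed the test. Reads of Wolbachia, an intracellular symbiont of insects, and of chloroplasts were left out of the community. Genotype accounted for 7.72% of the variation in Bray-Curtis distance (permutation test within diet and day, p = 1e-04, the smallest that these permutations can give), and day for 17.4% among normal-medium and restricted samples (permutation test, p = 1e-04). Restriction against normal medium accounted for 1.58% (permutation p = 0.218), recurrent against normal for 2.37% (permutation p = 0.228) and recurrent against restricted for 3.06% (permutation p = 0.182). Median distances were 0.510 within and 0.799 between groups. The Shannon index differed by 0.051 for tumour against control (permutation p = 0.753), by -0.323 for restriction against normal (permutation p = 0.0782) and by 0.097 for recurrent against normal (permutation p = 0.695). With Wolbachia reads kept, genotype accounted for 27.05% of the variation, and the Shannon differences for genotype (0.38, permutation p = 0.00521) and restriction (-0.325, permutation p = 0.0212) passed.

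Wolbachia separated the genotypes. It made up between 5.48% and 85.7% of all reads in the 40 control samples and at most 0.0797% in the 40 tumour samples. Among the other bacteria, the genera with a mean share of at least 1% were unclassified Xanthomonadaceae, Enterococcus, Lactobacillus, Burkholderia, Flavobacterium, unclassified Comamonadaceae, Acinetobacter, Staphylococcus, Pseudoalteromonas and reads without a class, at 38.6%, 14.5%, 14.1%, 7.26%, 2.19%, 1.84%, 1.2%, 1.19%, 1.07% and 1.05% of non-host reads. The planned test of genera, which gives each of the 16 groups its own coefficient, called 6 of 92 genera for genotype (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). It proved unreliable where a group held no reads of a genus. For genotype 76 of the 92 genera had such a group, and 61 of these had a p over 0.99, which is an untestable contrast and not evidence of equal levels. In simulated counts with 1 empty group per genus this test called 57 genera other than the 10 that were raised, against 5 for a model with the strata and a single term, which was chosen after this failure was seen. The strata model was itself without a usable test (SE over 100) for 0 to 5 of the 92 genera, depending on the contrast. Genera are therefore described as different only where both models called them. For genotype these were 3. Enterococcus, a fly gut genus, averaged 2.28% of reads in tumour samples and 26.8% in control samples, with reads in 12 and 32 of 40 samples (edgeR adjusted p = 2.67e-08 with the planned model and 0.000103 with the strata model). The tumour mean rested on 1 restricted pool at 6 days with 78.1%, and was 0.333% without it. The difference was not seen on the recurrent diet at 6 days (tumour 0.0484%, control 0.0166%). At 3 days control pools averaged 2.68% on normal medium and 0.5% under restriction, and tumour pools 0% and 0.00438%. Acetobacter, another fly gut genus, averaged 1.67% in tumour and 0.0191% in control samples, with reads in 25 and 14 of 40 (edgeR adjusted p = 1.19e-05 and 0.000997). Its tumour mean came almost only from normal medium at 6 and 10 days (3.18% ± 4.6 and 8.71% ± 6.45; SD, n = 5) and the recurrent diet at 6 days (1.39% ± 2.19). In restricted flies at 6 and 10 days it averaged at most 0.00712% in tumour and 0.00219% in control pools, so the difference is not one of every diet. Pelomonas averaged 0.0331% in tumour and 0.112% in control samples, with reads in 5 and 12 of 40 (edgeR adjusted p = 0.00523 and 0.0338). Without single replicate numbers the planned model kept Enterococcus and Acetobacter in 5 of 5 cases and Pelomonas in 2 of 5, so Pelomonas is uncertain. Burkholderia averaged 36.7% ± 34.8, 45.9% ± 30.6 and 33.1% ± 19.3 (SD, n = 5) in tumour flies at 6 days on the normal, restricted and recurrent diets, at most 0.355% in other tumour groups and at most 0.0127% in control groups. It had no usable planned test and passed with the strata model (edgeR adjusted p = 0.00736). Staphylococcus, Pedobacter and Flexispira were called by the planned model and not by the strata model (edgeR adjusted p = 0.272, 0.103 and 0.0659).

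For diet, the planned test called 4 genera under restriction, and the strata model called none of these 4, Acetobacter included (edgeR adjusted p = 0.00404 and 0.319), but 6 others. For the recurrent diet against normal medium 4 of its 8 genera were called by both models. Fluviicola (0.269% against 0.00811%), unclassified ACK-M1 (0.135% against 0.00978%) and unclassified Planococcaceae (0.141%, with 0 reads in the 20 normal-medium samples) were higher, and unclassified S24-7 (0.00187% against 0.519%) was lower, with strata model edgeR adjusted p between 0.00672 and 0.00907. For the recurrent against the restricted diet 3 of 4 were called by both, Fluviicola (0.269% against 0.0132%), Comamonas (0.0721% against 0.0143%) and unclassified Cytophagaceae (0.275% against 0.00971%). The other was Enterococcus, lower on the recurrent diet in the planned model (-5.22 ± 1.34 log2 units, edgeR adjusted p = 0.00788), for which the strata model had no usable test. It is not a result here: the planned call was lost without replicates 1, 2 and 5, with Wolbachia kept and with a replicate block (edgeR adjusted p = 0.336, 0.105, 0.0667, 0.0802 and 0.156). At 10 days the group means went the other way, at 47% ± 44.8 on the recurrent and 35.5% ± 48.7 on the restricted diet in control flies (SD, n = 5). The effect of restriction differed between genotypes in both models for Corynebacterium and unclassified Lachnospiraceae (strata model edgeR adjusted p = 0.0271 and 0.0192). These calls rest on few pools. Without single replicate numbers the planned model kept Fluviicola and S24-7 against normal medium in 5 of 5 cases, Planococcaceae in 3 and ACK-M1 in 1 of the 4 in which it was tested. Against the restricted diet it kept Fluviicola and Cytophagaceae in 3 of 5 and Comamonas in 0, and for the difference between genotypes Corynebacterium in 2 and Lachnospiraceae in 1. Regroupings of the samples did not exclude chance for the counts of any diet contrast (5 to 36 of 100 gave as many). Most of these genera made up well under 1% of reads, and each had reads in at most 12 samples of a side. In tumour flies at 10 days Lactobacillus, a fly gut genus, averaged 64.8% ± 24.7 under restriction and 4.3% ± 8.41 on the recurrent diet. At 6 days these were 5.9% ± 5.8 and 44.4% ± 25.6 (SD, n = 5). Exact permutation tests of the listed families and genera between 22 pairs of groups made 289 tests, of which 0 passed after adjustment and 43 had an unadjusted p under 0.05, the smallest p being 0.00794 (exact permutation, adjusted p = 0.135). No other tool was run on these pairs of groups. As 0.00794 is the smallest p that 5 against 5 pools can give, these tests could hardly pass the adjustment, and the count of 0 is no evidence of equal shares. Of the listed families, Lactobacillaceae and Enterococcaceae each had a mean share of 14.5%. The others had at most 2.15%: Comamonadaceae 2.15%, Staphylococcaceae 1.28%, Pseudomonadaceae 0.967%, Acetobacteraceae 0.922%, Propionibacteriaceae 0.848%, Corynebacteriaceae 0.429%, Enterobacteriaceae 0.0848% and Bradyrhizobiaceae 0.00876%.

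**Figure D5:**
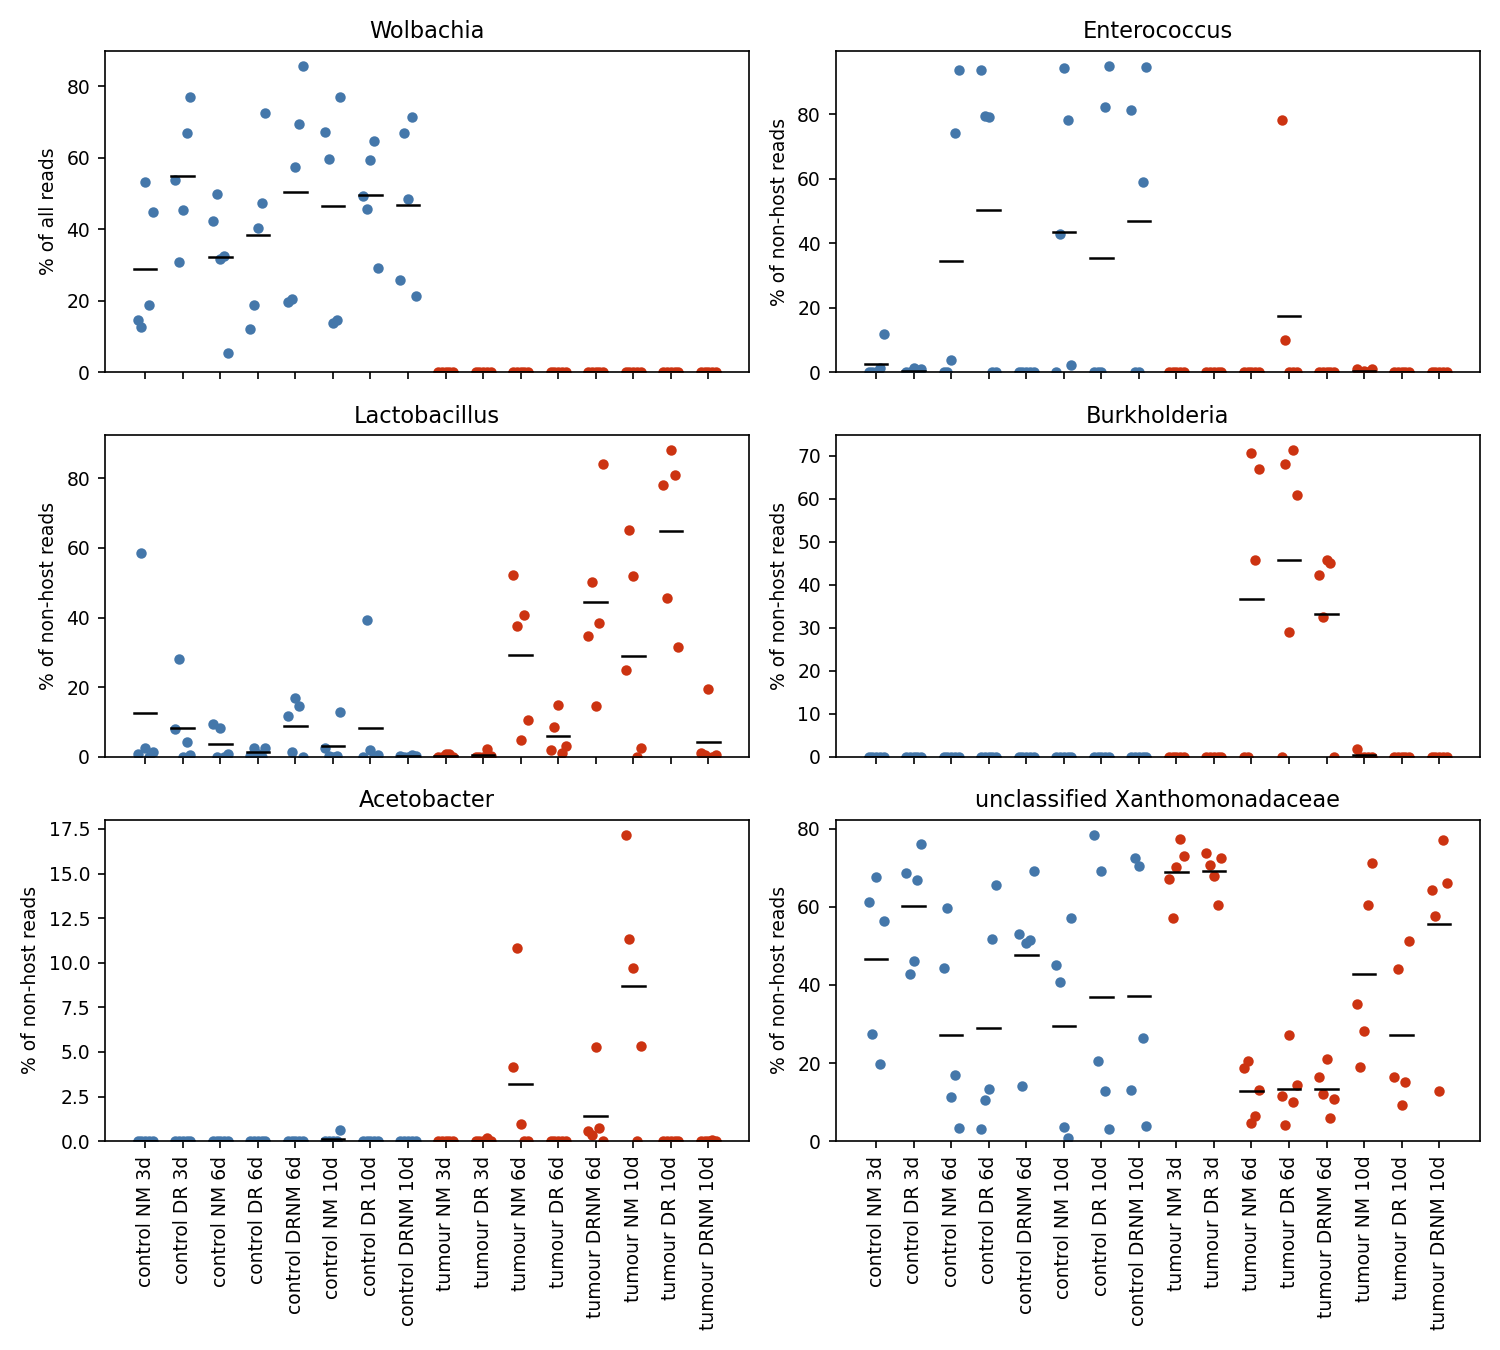
Share of reads in percent (linear axis) of 6 taxa in the 80 samples of 16S sequencing, 1 point per sample and 5 per group, with a line at each group mean; Wolbachia is a share of all reads and the others of non-host reads. Wolbachia lies between 5.48% and 85.7% in control samples and at most at 0.0797% in tumour samples, and Burkholderia averages 36.7% ± 34.8, 45.9% ± 30.6 and 33.1% ± 19.3 (mean ± SD) in tumour flies at 6 days on the normal, restricted and recurrent diets.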

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

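All tests of explanations in this part were chosen after the results were seen, except the regroupings of the RNA libraries, which were planned. Over 104 tests, each of a single measured value in a single group of 5 samples, 15 found a sample far from the others. Chance alone gives about 1 in 20 for independent, normally spread values. Shares with many zeros and related genes of the same library are not such values, so the 15 do not measure an excess over chance. In the recurrent tumour group, replicate 4 had 41.1 CPM of the hindgut gene byn (others 0.78 to 7.78), 150 CPM of the renal gene Uro (25.1 to 59.3) and 30.3 CPM of the yolk protein gene Yp1 (2.79 to 7.76). In 16S, control replicate 2 on normal medium at 3 days had a Shannon index of 1.58 (2.36 to 2.66) and 58.7% Lactobacillus. Lactobacillus also stood apart at 28.1% in restricted control replicate 2 at 3 days, 12.8% in normal-medium control replicate 5 at 10 days, 39.4% in restricted control replicate 2 at 10 days and 19.3% in recurrent tumour replicate 3 at 10 days. Enterococcus stood at 78.1% in restricted tumour replicate 1 at 6 days and 12% in normal-medium control replicate 5 at 3 days, and Acetobacter at 5.27% in recurrent tumour replicate 3 at 6 days. Staphylococcus stood at 6.69% in normal-medium tumour replicate 1 at 6 days and 66.3% in recurrent control replicate 2 at 6 days, and Pseudomonadaceae at 47.3% in normal-medium control replicate 4 at 3 days.

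Transcripts of hindgut and renal tubule varied between libraries of one group. Within groups, byn and the tubule list moved together over 30 libraries (Pearson 0.67, permutation p = 0.00216, adjusted over 6 relations p = 0.0031; Spearman 0.6, permutation p = 0.00562, adjusted p = 0.00674; 0.57 without the 2 farthest libraries). Byn did not follow reads per library (Pearson 0.02, permutation p = 0.937, adjusted p = 0.937; Spearman 0.04, permutation p = 0.84, adjusted p = 0.84; 0.07 without the 2 farthest), which argues against library size. Tissue left on some dissected midguts is a candidate explanation. Of the 4226 genes whose restriction effect differed between genotypes, 4161 stayed called with the hindgut level as a covariate and 3964 with the tubule level. The measured levels thus did not account for most of these calls. The hindgut covariate rests on byn and otp alone, so a remaining effect of such tissue was not excluded.

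Wolbachia made up over 1% of reads in every control pool and in no tumour pool. That 0 pools lay on the other side of 1% restates this, so an exchange of genotype labels as a whole was not excluded. An infection inherited from a parent of the control cross may explain it, but 0 groups held both kinds of pool, so infection and genotype cannot be told apart, and bacterial differences between genotypes may follow either.

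Unclassified Xanthomonadaceae were present in every 16S sample. Within groups their share followed Comamonadaceae (Spearman 0.46, permutation p = 0.00039, adjusted over 6 relations p = 0.00078; Pearson 0.41, permutation p = 0.00209, adjusted p = 0.0031; Pearson 0.46 without the 2 farthest of 80 samples) and fell with reads per sample (Spearman -0.38, permutation p = 0.00179, adjusted p = 0.00268; Pearson -0.36, permutation p = 0.00258, adjusted p = 0.0031; Pearson -0.32 without the 2 farthest). In the 40 control pools it followed Wolbachia (Pearson 0.71, Spearman 0.72, both permutation p = 1e-05, the smallest they can give, adjusted p = 6e-05, and Pearson 0.74 without the 2 farthest). These relations decide nothing: Enterococcus fills up to 94.9% in a pool, so other shares can move together, or with reads, whatever their source. Xanthomonadaceae fell with Enterococcus (Pearson -0.65, Spearman -0.53). Bacteria of water or reagents, seen where gut bacteria were few, and an effect of depth therefore stay open. No biological explanation was tested.

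Effects differed between groups by tests of the difference. The restriction effect differed between genotypes for 4226 genes and the recurrent diet effect for 86. Among genes selected on normal medium the tumour difference on the recurrent diet minus that on the restricted diet was -0.16 (limma's fry, adjusted p = 0.0427, lost when any 1 of 10 libraries was left out), among those selected under restriction it was 0.1 larger on the recurrent diet than on normal medium (adjusted p = 0.0282), and among those selected on the recurrent diet it was 0.38 larger under restriction than on normal medium (adjusted p = 2.81e-07). For genera the planned test called 2 restriction effects that differed.

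Other groupings of the same libraries, 100 per contrast with the real grouping as 1 of them, excluded chance for these counts, given with the highest other count: tumour against control 2963 (1146) on normal medium, and, as a share of the tested genes, 66.5% (39.8%) on the restricted and 39.3% (18.5%) on the recurrent diet, tumour flies 4476 (2764), 263 (297, with 2 of 100 as large) and 4760 (1298), and control flies 5219 (3019), 2434 (1340) and 4825 (3176). For the interactions, 4226 (695) and 86 (2520, with 3 of 100 as large), genotype labels were exchanged within each diet. That also removes the genotype effect itself, so these regroupings cannot exclude chance for the interaction counts. An uneven exchange between diets can also turn the genotype effect into a difference of diet effects. The regrouping that called 2520 genes therefore cannot be set against the real 86. For 16S genera, with the planned model, the count for genotype exceeded the others by 1 genus (6, highest other 5). This narrow margin, from a model that was unreliable for groups without reads, concerns the count and no single genus. Chance was not excluded for restriction (4, 8; 15 of 100 as large), the recurrent diet against normal medium (8, 12; 5 of 100), the recurrent against the restricted diet (4, 8; 12 of 100) or the difference between genotypes (2, 5; 36 of 100).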

How the results depend on the processing

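The covariates for neighbouring tissue, the set without libraries far from their group in byn, the strata model for genera, and leaving out libraries for lists, signature and overlap were added after the data were seen. Unless stated, the cause of a change was not tested. With the second diet label, counts went to 2409 (tumour against control, recurrent diet), 2679, 35 and 2675 (tumour flies: restricted and recurrent against normal, recurrent against restricted), 953 and 3060 (control flies: recurrent against normal and against restricted), 2776 and 9 (differences between genotypes under restriction and the recurrent diet). Amyrel then had 0.55 in place of -3.46 ± 0.39 in the difference under restriction. Without the 4 normal-medium libraries numbered in the run of the other genotype, whose w levels match their titles, the normal-medium tumour count was 1890 and the recurrent difference 13. With the run of library numbers as a covariate, the recurrent tumour count was 2536 and the recurrent difference 26. With only the groups compared, the recurrent count of tumour flies was 118. The recurrent difference was 230 with DESeq2, 273 with the hindgut covariate, 156 with the tubule covariate and 20 without libraries far from their group in byn. Raf on normal medium was 0.05 without these libraries, against a value of -0.05.

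Replicate numbers gave no common sign of pairing. Over the 8 contrasts with 5 pairs, the median correlation of deviations at the same number went from -0.329 (recurrent against restricted, control flies; 0.192 at other numbers) to 0.235 (recurrent against normal, tumour flies; -0.036 at other numbers), and the single pair on normal medium had 0.327. Pairing was therefore not excluded for every contrast. With the number as a replicate block, the recurrent difference was 38 genes and the difference between genotypes 1 genus, and the other counts moved by at most 1.5 times.

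Leaving out each library gave ranges of 2433 to 3259, 6215 to 6381 and 3514 to 3862 genes for tumour against control, 3991 to 4747, 91 to 345 and 4269 to 4556 for diets in tumour flies, 4853 to 5160, 1743 to 2821 and 4487 to 4911 in control flies, and 3912 to 4292 and 47 to 181 for the differences. The recurrent count of tumour flies was 91 without recurrent replicate 3, 103 without normal-medium replicate 4b and 120 without replicate 5. The recurrent difference was 181, 47 and 54 without control recurrent replicates 4, 3 and 1, 50 without control normal-medium replicate 5 and 55 without tumour recurrent replicate 5. Raf on normal medium ranged from -0.09 to 0, the latter without tumour replicate 3a. The signature difference selected on normal medium ranged from -0.18 to -0.15, with the call lost for 10 of the 30 libraries. With genes selected at an adjusted p under 0.01 and at least 2-fold, the differences were -0.44, 0.25 and 0.92 for genes selected on normal, restricted and recurrent diets, against -0.16, 0.1 and 0.38, in the same directions.

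Of the 112 list calls, 4 remained in number with an estimated correlation, and fry, which asks another question, called 169. For 16S, keeping Wolbachia took the Shannon difference to 0.38 (genotype) and -0.325 (restriction), both past the threshold. Leaving out replicates gave Shannon ranges of -0.013 to 0.095 (genotype) and -0.081 to 0.254 (recurrent against normal), which change sign, and of -0.406 to -0.149 (restriction), the last without replicate 1 (permutation p = 0.48). Genus counts moved with most settings. For genotype they were 25 with DESeq2, 17 with the strata model and 2 to 7 without single replicates. For restriction they were 1 with genera of at least 1 read, 2 at OTU level, 17 with DESeq2 and 0 to 3 without replicates. For recurrent against normal they were 5 with Wolbachia kept, with DESeq2 size factors, with at least 1 read, at OTU level and with a minimum of 3000 reads, 25 with DESeq2 and 3 to 7 without replicates. For recurrent against restricted they were 21 with DESeq2, 10 with the strata model and 1 to 3 without replicates. For the difference they were 4 with at least 1 read and at OTU level, 0 with a minimum of 3000 reads, 22 with DESeq2, 19 with the strata model and 0 to 5 without replicates. Groups without reads enter each of these models differently, so genus counts are not a firm measure.

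Of the settings for genes named in the text other than leaving out a library, 4063 values kept direction and call, 155 lost the call, 4 gained it and 2 changed sign, and with a library left out 3855 kept both, 119 lost the call, 5 gained it and 1 changed sign. For the genera called by the planned model, 124 values kept the call and 43 lost it, and without single replicates 52 kept and 64 lost it.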

Other observations

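The genes p38c and Marf1 differed between genotypes in the same direction on each diet. The stress kinase gene p38c stood at 53.1 ± 5.63 CPM in control and 1.83 ± 0.175 CPM in tumour flies on normal medium, with log2 differences of -4.85 ± 0.14, -3.60 ± 0.13 and -5.24 ± 0.14 on the normal, restricted and recurrent diets. Marf1 had log2 differences of 3.15 ± 0.24, 2.39 ± 0.25 and 3.34 ± 0.25. The control and tumour flies came from crosses to different strains, and genes of this kind were not tested for strain differences here.

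If the recurrent cycle began with restriction, days 6 and 13 lay in the normal-medium phase and day 10 in the restricted phase. This was not tested.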
